A study of Mus musculus with 6 samples.

How the data were processed

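RNA from perfused right lung lobes of 6-week-old mice was sequenced in 6 libraries, 3 from Col6a1-/- animals and 3 from wildtype C57BL/6 animals, per the labels' protocols. Each library held RNA pooled from 2 animals of 1 genotype, and each animal went into 1 pool, so the 12 animals gave 3 separate biological pools per genotype. Sex was not given in the labels.

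The submitters' processing notes list Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.0p3 with featureCounts, R 3.4.1, DESeq2 1.16.1 and the build GRCm38.p5, with no role or order for any of them. The annotation release, the strand setting of the counting and the design formula are not given in the sources used here. The deposited signal per gene and library was a normalized count made by the authors with DESeq2, per the name of the deposited table. The header of wildtype replicate 2 carried the added word New, and what it refers to is not given in the sources used here. All values (100% in each library, to within 1e-06 of a whole multiple) were whole reads divided by 1 size factor per library, and the size factors ran from 0.911 to 1.25. For Col6a1-/- replicate 3 the size factor was 1.0003, so that its steps lay too close to 1 for the step alone to test the recovery. The recovered reads were used only for depth and for count models run as alternatives. Depth was 28055414 to 37904878 reads in genes per library, and the 10 most abundant genes held 6.6% to 8.26% of each library. The authors' deposited table of Col6a1-/- against wildtype held a mean of normalized counts and a test statistic per gene, both a score here, a log2 fold change, and a p-value with its adjusted value. Its means equalled those of the 6 deposited columns to within 4.7e-10.

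The table had 49568 rows, of which 28476 were above 0 in at least 1 library, and no row without a gene name. Genes with a normalized count of at least 10 in at least 3 libraries were tested, which left 16879. The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), two-sided, without covariates, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on that log2 scale, which understates the change of genes with low counts. Percentages of the wildtype level are ratios of mean normalized counts. Errors beside means are SDs over 3 libraries, and SE is the standard error of the limma coefficient.

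The main test, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except for the alternatives and the 2 gene groups named as added below. The 41 gene lists with 749 entries were for the lung matrix, lung cell types, neighbouring tissues and common programmes. Of the entries, 2 (Ahsp and Snorc) had no match in the table. The sex-linked list (Xist and 4 Y-linked genes) was a check of the pools and was not tested. The other 40 lists were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided and Benjamini-Hochberg adjusted over the 40 lists. Camera with an estimated correlation and the rotation test fry were alternatives. The share of called genes within 5 Mb of Col6a1 was compared with that of the remaining genes by a two-sided Fisher's exact test, with Col6a1 left out and a continuity correction in the odds ratio.

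Genes were named by a fixed rule: Col6a1 and the other collagen VI chains, all called genes, the genes with the smallest unadjusted p where fewer than 6 were called in a direction (mean normalized count of at least 50, no overlap between genotypes, no predicted-gene symbol), leading members of the lists, called genes near Col6a1 and the sex-linked genes. One of the genes this rule names is not reported here. Gene identifiers, positions, transcript length and GC content came from GENCODE M21 on GRCm38, the same assembly as in the processing notes, and 95.3% of the rows matched it by symbol. The length and GC of a gene are those of its longest transcript, known for 97.4% of the tested genes.

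The fixed alternatives were pseudocounts of 0.5 and 5, no filter on low values and a filter at 50, median centring, quantile normalization, robust moderation, library quality weights, edgeR 4.0.16 on the recovered reads of the tested genes, DESeq2 1.42.0 on the recovered reads of all 28476 genes above 0, the replicate number as a block, each library left out, other thresholds and other windows. Alternatives chosen after seeing the data were the male share of each pool as a covariate, the 3 pools of mixed sex alone, DESeq2 on the genes of the main filter, and removal of a smooth trend of each library on transcript length and GC (natural splines with 5 degrees of freedom each). The male share was the mean level of the 4 Y-linked genes relative to Col6a1-/- replicate 2, the library with the lowest Xist. Heat shock factor targets with cold-inducible genes, and clock genes of large amplitude, were the 2 gene groups chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

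The main test was tested on simulated data for 3 against 3 libraries, with counts drawn for the 16879 genes at the observed means, depths and dispersions and 200 genes changed. It called 28% of the genes changed by a log2 fold of 0.5, 96% at 1 and 100% at 2 and 3. Over 10 further simulations 7.2% of its calls were false, with a range of 4.07% to 11.1%. For lists, 20 of 20 simulated shifted lists and 0 of 100 unchanged lists were called with either correlation, in simulated genes that vary independently.

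Gene counts do not show exons, so the counts of Col6a1 sum over all parts of the gene. The targeted part of Col6a1 is not given in the sources used here. Near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b) share reads and their single values are uncertain, as are those of genes that overlap others on either strand.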

Results

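Lungs of Col6a1-/- mice were compared with wildtype lungs. Col6a1 encodes a chain of collagen VI. Collagen VI is a microfibrillar collagen found beside basement membranes, and its usual form is a heterotrimer of the chains encoded by Col6a1, Col6a2 and Col6a3. Gene expression was read as DESeq2-normalized counts in 3 libraries per genotype, each a pool of 2 animals, at 28055414 to 37904878 reads in genes per library. The first principal component of the log2 values held 39.5% of the variance and the second 24.7%. The correlation between libraries across genes was 0.988 to 0.994 within genotypes and 0.983 to 0.993 between them.

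Col6a1 (ENSMUSG00000001119.7, chromosome 10, 76708792 to 76726168, minus strand, GRCm38) was lower in every Col6a1-/- library than in every wildtype library. Its normalized counts were 10034, 10616 and 9344 in Col6a1-/- replicates 1, 2 and 3, and 19907, 18393 and 22330.5 in wildtype replicates 1, 2 and 3. The mean in Col6a1-/- lungs was 49.5% of the wildtype mean, 9998 ± 637 against 20210.3 ± 1986 (SD, n = 3 pools each). The log2 fold change was -1.01 with an SE of 0.10 and a limma adjusted p of 0.00643. Col6a2 (ENSMUSG00000020241.13, chromosome 10, 76595762 to 76623630, minus strand) fell by 0.86 on the log2 scale, to 55.0% of wildtype, with an SE of 0.12 and a limma adjusted p of 0.0435. Its mean was 9519.8 ± 1091 in Col6a1-/- and 17312 ± 2279 in wildtype lungs (SD, n = 3 each). Col6a3 stood at 77.5% of wildtype, with overlapping libraries and an adjusted p of 0.141, and was not called. Col6a4, Col6a5 and Col6a6 were low in both genotypes, with wildtype means of 82.0, 51.0 and 41.0 normalized counts, log2 fold changes of -0.07, -0.05 and -0.13, and adjusted p of 0.905, 0.936 and 0.76. The sign of these 3 small estimates turned positive when the trend on transcript length and GC was removed, at 0.15, 0.16 and 0.11.

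In all, 11 of 16879 tested genes passed the limma threshold, 8 lower and 3 higher in Col6a1-/- lungs. Beside the collagen VI chains, the lower genes were Capn11, Clca1, Lrp2, Hsph1, Slc6a2 and Vwf. Vwf, the von Willebrand factor of endothelial cells, fell from 24045 ± 737 to 15186 ± 1158 normalized counts, a log2 fold change of -0.67 with an SE of 0.09 and an adjusted p of 0.0468. Its log2 fold change was -0.43 with the trend on transcript length and GC removed (limma adjusted p 0.0445). Hsph1, a heat shock protein of the Hsp110 family, fell to 56.8% of wildtype (log2 fold change -0.81, SE 0.09, adjusted p 0.0105). Lrp2, the endocytic receptor megalin, stood at 54.4% and Slc6a2, the noradrenaline transporter, at 59.7% of wildtype, with adjusted p of 0.0215 and 0.0481. Clca1, a secreted product of goblet cells, fell to 22.3% of wildtype (log2 fold change -2.08, SE 0.26, adjusted p 0.0215), with 474 normalized counts in wildtype replicate 3 against 1059 and 1006 in wildtype replicates 1 and 2. With the male share of each pool as a covariate the log2 fold change of Clca1 was -1.27 with an adjusted p of 0.547, and in the mixed-sex pools alone it was -1.32. Capn11, a calpain protease, had the largest fold change among the called genes at -4.42, with an SE of 0.42 and an adjusted p of 0.00643. Its reads numbered 5 over the Col6a1-/- libraries and 153 over the wildtype libraries, a ratio of 3.01% after scaling, with an exact 95% interval of 0.962% to 7.17% that covers counting error only.

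The 3 genes called higher were Igha, Sult1d1 and Gm44220. Igha, the constant region of the immunoglobulin A heavy chain, rose 2.56-fold, from 182 ± 19.2 to 467 ± 49.5 normalized counts (SD, n = 3 each), with a log2 fold change of 1.35, an SE of 0.13 and a limma adjusted p of 0.00643. Sult1d1, a cytosolic sulfotransferase, rose 2.03-fold (log2 fold change 1.02, SE 0.13, adjusted p 0.0215), and the predicted gene Gm44220 rose 1.64-fold (log2 fold change 0.72, SE 0.10, adjusted p 0.0435). Next by unadjusted p, and not past the threshold, were Pigp at 1.66-fold, the cold-inducible RNA-binding gene Cirbp at 1.5-fold and the growth factor binding gene Fgfbp3 at 2.04-fold, each with an adjusted p of 0.0681. Without the trend on transcript length and GC, Sult1d1 and Gm44220 had log2 fold changes of 0.20 and 0.34 and were no longer called, with adjusted p of 0.679 and 0.165.

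**Figure D1:**
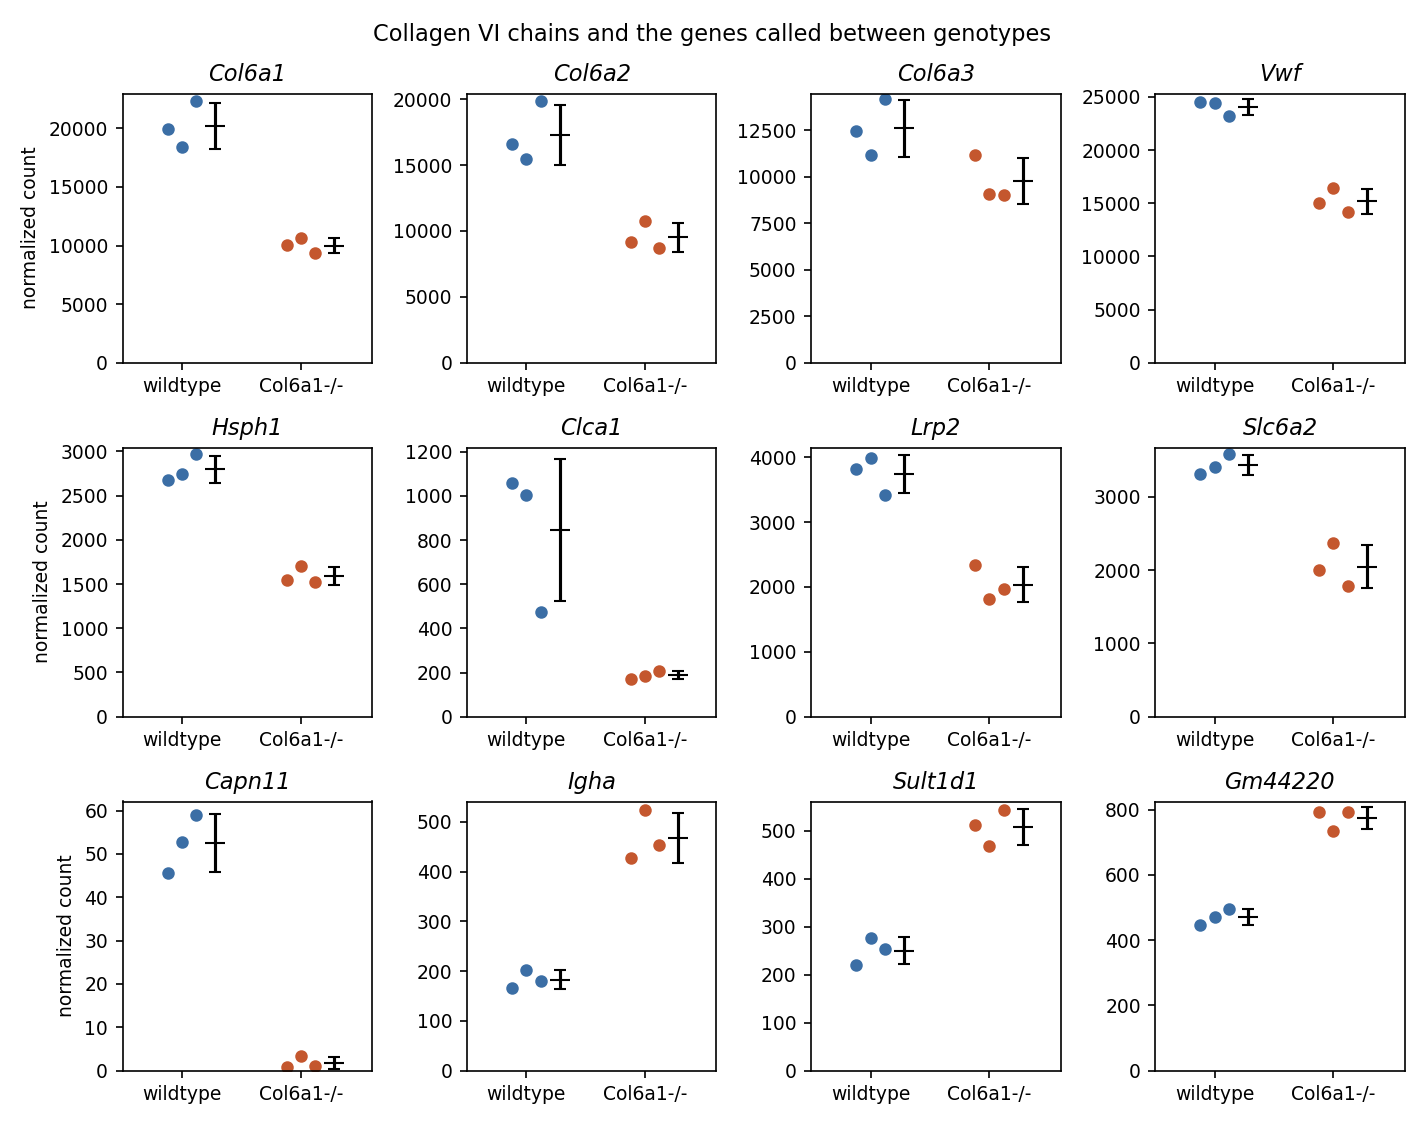
Normalized counts (vertical axes, linear and from 0) of Col6a1, Col6a2, Col6a3 and the other called genes in the 3 wildtype libraries (blue) and the 3 Col6a1-/- libraries (orange), with the mean and SD in black beside the points. Col6a1 lay between 9344 and 10616 in Col6a1-/- and between 18393 and 22330.5 in wildtype lungs.

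The number of called genes depended on single libraries. No gene was called by limma without wildtype replicate 1 (1902 genes at an unadjusted p under 0.05) or without Col6a1-/- replicate 3 (1979 genes), 2 were called without wildtype replicate 2, 1383 without wildtype replicate 3, and 13 and 47 without Col6a1-/- replicates 1 and 2. The excess of lower genes did not hold in all of these fits: 886 were higher and 497 lower without wildtype replicate 3, and 23 were higher and 24 lower without Col6a1-/- replicate 2. Without wildtype replicate 3, sex and genotype cannot be told apart. The male share was 0.347% and 3.35% in the remaining wildtype pools and 51.1% to 100% in the Col6a1-/- pools. Col6a1 kept a log2 fold change between -1.08 and -0.94 in the fits that left out a library, with an adjusted p of 0.066 without wildtype replicate 1 and 0.123 without Col6a1-/- replicate 3. Capn11 was not tested in the fits that left out a wildtype library. The filter there still asked for a normalized count of at least 10 in 3 libraries, and Capn11 did not reach 10 in any Col6a1-/- library. In the full set, 3430 genes had an unadjusted p under 0.05, where chance alone gives 844 on average. The libraries of the genotypes did not overlap for 24.9% of genes, where chance gives 10% on average. Genes do not vary independently, so these excesses are not a test, and they do not separate genotype from the sex of the pools. Median centring of the libraries gave 26 called genes, 3 higher and 23 lower, and library quality weights gave 3225, 1669 higher and 1556 lower. edgeR on the recovered reads called 13 genes, 11 of them shared with the 11 above.

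In the authors' deposited table, 742 of 14679 genes with an adjusted p had one under 0.05, 275 higher and 467 lower in Col6a1-/- lungs. Of the 11 genes called above, 10 were among the genes called in the authors' deposited table; Capn11 had no adjusted p there. All 742 had the same sign and an unadjusted p under 0.05 in the limma fit, and 711 had no overlap between the genotypes. Both come from the same 6 libraries, so this overlap is not independent support for the calls. DESeq2 on the recovered reads of all genes above 0 called 742 genes (739 on the genes of the limma filter), and all 742 were those called in the authors' deposited table. Fold changes in the authors' deposited table were smaller, with a median ratio of 0.875 to the unshrunken DESeq2 values and of 1.00 to the values with DESeq2's normal prior on the fold change. Clca1, for example, had a log2 fold change of -1.48 in the authors' deposited table.

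Of the 40 gene lists, 17 passed the camera test, 11 lower and 6 higher in Col6a1-/- lungs; none passed with an estimated correlation, for which the smallest adjusted p was 0.399, and none passed fry's directional test. Matrix lists lay lower. In the basement membrane list, 26 of 27 tested members had lower estimates, with a median log2 fold change of -0.27 and a camera adjusted p of 1.46e-08 (adjusted p = 0.399 with an estimated correlation). No member was called over all genes, and 12 were called, all lower, adjusted over the list alone. The median of the basement membrane list was -0.18 without Col6a1-/- replicate 3. Its members that did not pass over all genes included the laminin chain genes Lama1 at 41.4% and Lama3 at 74.5% of wildtype, with adjusted p of 0.0815 and 0.0942. In the integrin list, 16 of 20 members had lower estimates (median log2 fold change -0.24, camera adjusted p 0.000346, and adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone, 6 of its members were lower and 1 higher. Itga6 stood at 72.5% and Itga7 at 71.5% of wildtype, with adjusted p of 0.0815 and 0.095.

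The list of collagen VI receptors and partners (14 of 20 lower, median -0.16, camera adjusted p 0.00734) held members that went in opposite directions. It shared 8 members with the integrin list, so these lists are not independent. Fn1, fibronectin, stood at 61.3% of wildtype with an adjusted p of 0.0693, while Dcn, decorin, was 1.39-fold the wildtype level with an adjusted p of 0.0781. Adjusted over the list alone, 5 of its members were lower and 1 higher. The elastic fibre list (19 of 22 lower, median -0.17, camera adjusted p 0.00112) had 4 lower members adjusted over the list alone, and its members Loxl4 and Fbn1 stood at 62.2% and 69.4% of wildtype, with adjusted p of 0.117 and 0.118. The interstitial collagens (13 of 16 lower, median -0.15, camera adjusted p 0.0088) had no member called adjusted over the list alone, and Col12a1 and Col5a1 stood at 74.5% and 79.0% of wildtype with adjusted p of 0.108 and 0.154. The matrix proteases and inhibitors (22 of 29 lower, median -0.16, camera adjusted p 0.00112) had 3 lower members adjusted over the list alone, and the metalloproteases Adamts9 and Adamts15 stood at 62.0% and 56.1% of wildtype with adjusted p of 0.0833 and 0.0939. The median of the matrix proteases and inhibitors was -0.10 without wildtype replicate 3 and -0.26 without wildtype replicate 2, and that of the collagen VI partners was -0.24 without Col6a1-/- replicate 2. All 6 collagen VI chains had lower estimates (median -0.25, camera adjusted p 0.00238), with 2 called over all genes and 3 adjusted over the list alone, and without Col6a1 the unadjusted camera p of the other 5 was 0.0194, or 0.213 with an estimated correlation. Each of these 5 lists had an adjusted p of 0.399 with an estimated correlation.

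The oxidative phosphorylation list lay higher, with 26 of 29 members above wildtype, a median log2 fold change of 0.15 and a camera adjusted p of 7.04e-05 (adjusted p = 0.474 with an estimated correlation). It had 3 higher members adjusted over the list alone, and Cox6c and Ndufa4 were 1.42-fold and 1.3-fold the wildtype level with adjusted p of 0.0893 and 0.108. The median of the oxidative phosphorylation list was 0.23 without Col6a1-/- replicate 1 and 0.099 without Col6a1-/- replicate 3. The mean level of the oxidative phosphorylation list, relative to the mean of the 6 libraries, was -0.05, -0.09 and -0.13 in wildtype replicates 1, 2 and 3 and -0.06, 0.12 and 0.20 in Col6a1-/- replicates 1, 2 and 3, so that Col6a1-/- replicate 1 lay within the wildtype range. In the same order the level of the cardiac muscle list was -0.02, -0.17 and -0.32 in wildtype and 0.10, 0.17 and 0.24 in Col6a1-/- lungs. Transcripts of the mitochondrial genome took 1.18%, 1.09% and 1.99% of reads in genes in wildtype replicates 1, 2 and 3 and 2.29%, 1.88% and 2.17% in Col6a1-/- replicates 1, 2 and 3 (exact permutation test, two-sided, p = 0.2, smallest possible 0.1). Fold changes across all genes followed transcript length and GC content. Among 12730 genes with a mean of at least 100, Spearman's rho with the log2 fold change was -0.354 for length and -0.350 for GC (across genes, which are not independent replicates). The median transcript length was 6615 bases in the basement membrane list, 5794 in the interstitial collagens and 1661 in the oxidative phosphorylation list, against 3464 bases in those 12730 genes. After the trend was removed from each library, the basement membrane, elastic fibre, interstitial collagen, collagen VI chain, collagen VI partner and oxidative phosphorylation lists no longer passed (adjusted p of 0.0985, 0.0834, 0.935, 0.0834, 0.0729 and 0.126), while the integrins and the matrix proteases did (0.00338 and 0.00482). The collagen VI partner list was also lost without wildtype replicate 3, at an adjusted p of 0.0883.

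**Figure D2:**
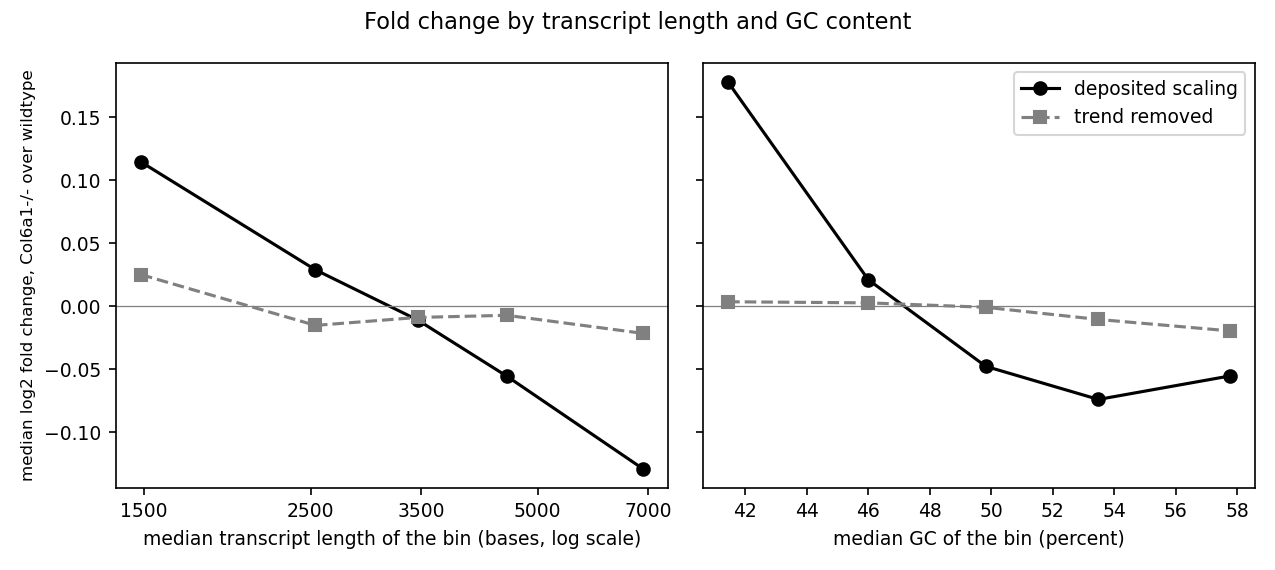
Median log2 fold change of Col6a1-/- over wildtype (vertical axis) in 5 bins of 2546 genes by transcript length in bases (left, log axis) and by GC percent (right), before (black circles) and after (grey squares) the trend of each library was removed. The shortest bin had a median of 0.11 and the longest of -0.13 before removal, and 0.025 and -0.021 after it.

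The red cell, fat tissue and cardiac muscle lists lay higher in Col6a1-/- lungs. Blood left after perfusion and neighbouring tissue taken with the lung cannot be told apart here from a change in the lung itself. All 10 tested red cell genes had higher estimates, with a median log2 fold change of 0.78 and a camera adjusted p of 1.46e-08. No member was called over all genes and 8 were higher adjusted over the list alone. The beta and alpha globin genes Hbb-bs and Hba-a1 were 1.96-fold and 1.78-fold the wildtype level, with adjusted p of 0.0781 and 0.0786. Fat tissue genes (12 of 14 higher, median 1.15, camera adjusted p 1.72e-05) included the fatty acid binding protein gene Fabp4 at 2.3-fold, Retn at 2.75-fold and Car3 at 2.32-fold, with adjusted p of 0.0792, 0.0869 and 0.0869, and 7 of them were higher adjusted over the list alone. Without wildtype replicate 3 the fat tissue median was 0.67 (camera adjusted p 0.00217). Cardiac muscle genes (15 of 16 higher, median 0.35, camera adjusted p 1.38e-06) included Myl4 at 1.39-fold and Tnnc1 at 1.53-fold, with adjusted p of 0.0939 and 0.0954, and 11 were higher adjusted over the list alone. These 3 lists had an adjusted p of 0.399 with an estimated correlation, and they passed camera in each of the 6 fits that left out a library. The mean level of the fat tissue list was lowest in wildtype replicate 3, at -0.95 on the log2 scale relative to the mean of the 6 libraries, and highest in Col6a1-/- replicate 2, at 0.77.

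Among immune lists, the B and plasma cell list lay lower (16 of 19 members, median -0.35, camera adjusted p 0.000148, and adjusted p = 0.399 with an estimated correlation). The B cell transcription factor genes Pax5 and Spib stood at 55.9% and 49.8% of wildtype and the kinase gene Blk at 60.7%, with adjusted p of 0.0681, 0.0681 and 0.0812, while Igha, a member of the same list, rose. Over all genes 1 member was higher and none lower; adjusted over the list alone, 3 were higher and 9 lower. The mean level of the B and plasma cell list, relative to the mean of the 6 libraries, was 0.20, 0.17 and -0.08 in wildtype replicates 1, 2 and 3 and -0.06, -0.22 and 0.0040 in Col6a1-/- replicates 1, 2 and 3, so that wildtype replicate 3 lay below Col6a1-/- replicates 1 and 3. The alveolar macrophage list (13 of 18 lower, median -0.17, camera adjusted p 0.0088) had 3 lower members adjusted over the list alone, and Krt79 and the scavenger receptor gene Marco stood at 68.6% and 73.9% of wildtype with adjusted p of 0.0942 and 0.108. The dendritic cell and MHC class II list (14 of 18 lower, median -0.16, camera adjusted p 0.0135) had 1 lower member adjusted over the list alone, Ciita, the transactivator of MHC class II genes, at 66.4% of wildtype with an adjusted p of 0.0833 over all genes. With an estimated correlation the adjusted p of the alveolar macrophage and dendritic cell lists was 0.399 and 0.474. With the male share of each pool as a covariate, none of these 3 lists passed (adjusted p of 0.692, 0.181 and 0.738), with medians of -0.09, -0.07 and 0.026. The alveolar macrophage list was also lost without Col6a1-/- replicate 1 or 2 (0.0577 and 0.0506) and the dendritic cell list without wildtype replicate 1 or Col6a1-/- replicate 2 (0.0931 and 0.0911).

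Airway epithelial lists lay higher and the cell cycle list lower. In the ciliated cell list, 16 of 20 members had higher estimates (median 0.20, camera adjusted p 0.00767, and adjusted p = 0.511 with an estimated correlation), with 2 higher adjusted over the list alone. Sntn and Mlf1 were 1.78-fold and 1.48-fold the wildtype level with adjusted p of 0.0693 and 0.0781. In the club and secretory cell list, 14 of 18 members had higher estimates (median 0.20, camera adjusted p 0.0274, and adjusted p = 0.474 with an estimated correlation). The secretoglobin gene Scgb3a2 was 1.51-fold the wildtype level and the immunoglobulin receptor gene Pigr 76.3% of it, with adjusted p of 0.0809 and 0.143, and 3 members were higher and 1 lower adjusted over the list alone. In the cell cycle list, 21 of 24 members had lower estimates (median -0.22, camera adjusted p 0.0135, and adjusted p = 0.64 with an estimated correlation), none was called adjusted over the list alone, and Mki67 and Aurkb stood at 67.3% and 65.6% of wildtype with adjusted p of 0.203 and 0.159. Without wildtype replicate 3 the medians of the ciliated, club and cell cycle lists were 0.072, 0.15 and -0.03, and none of them passed (adjusted p of 0.467, 0.688 and 0.794). Without Col6a1-/- replicate 2 the club and cell cycle lists did not pass either (medians of 0.21 and -0.11, adjusted p of 0.0527 and 0.325), nor did the club list after the length and GC trend was removed (0.0573). With the male share as a covariate the medians of the ciliated, club and cell cycle lists were larger in size, at 0.45, 0.33 and -0.36.

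**Figure D3:**
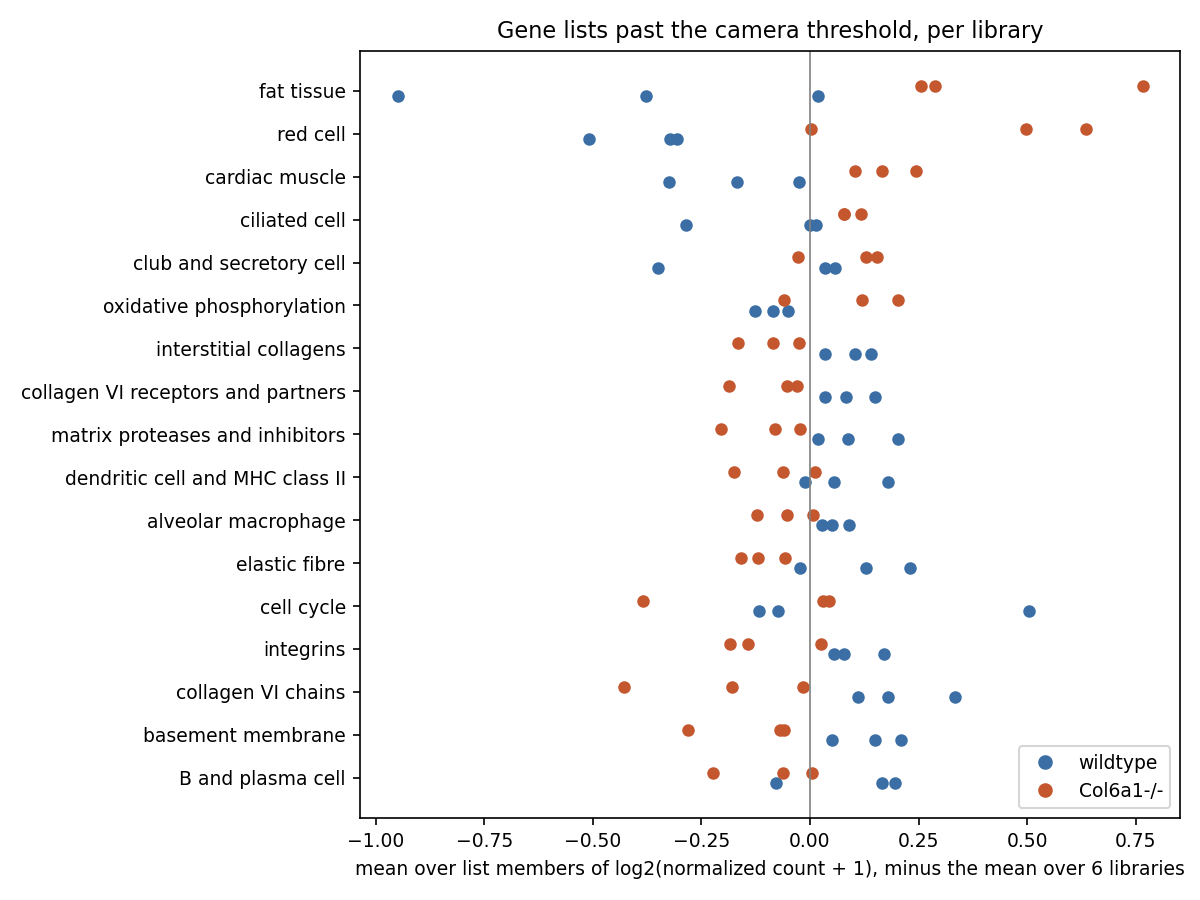
Mean log2 level of the members of each of the 17 lists that passed camera (vertical axis) in each library, relative to the mean over the 6 libraries (horizontal axis, log2 units), with wildtype in blue and Col6a1-/- in orange. For the red cell list the wildtype libraries lie between -0.51 and -0.31 and the Col6a1-/- libraries between 0.0019 and 0.64, while for the cell cycle list wildtype replicate 3 at 0.50 and Col6a1-/- replicate 2 at -0.39 stand apart.

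The other 23 lists did not pass camera. Among lung cell types, the adjusted p was 0.0703 for alveolar type 2 cells, 0.222 for alveolar type 1 cells, 0.156 for blood endothelium, 0.195 for lymphatic endothelium, 0.818 for alveolar and matrix fibroblasts, 0.343 for smooth muscle and myofibroblasts, 0.415 for pericytes, 0.119 for mesothelium and 0.119 for nerve and Schwann cells. Among leukocytes it was 0.156 for monocytes and interstitial macrophages, 0.6 for neutrophils, 0.298 for T and NK cells and 0.818 for mast cells and basophils. Skeletal muscle (0.222), thymus (0.779) and cartilage (0.14) did not pass either. The programmes that did not pass were autophagy and mitophagy (0.0621), sterol and fatty acid synthesis (0.0745), the circadian clock (0.209), immediate early and heat shock genes (0.231), the interferon response (0.261), TGF-beta and YAP targets (0.298) and Wnt and BMP signalling (0.32). With the male share of each pool as a covariate 20 of the 40 lists passed, 12 higher and 8 lower, 14 of them shared with the 17. The 6 further lists, all higher in that fit, were neutrophils (median 0.80, adjusted p 1.52e-08), T and NK cells (0.35, against -0.11 without the covariate, adjusted p 0.000203), the interferon response (0.24, adjusted p 4.09e-05), mesothelium (0.19, adjusted p 0.00596), smooth muscle and myofibroblasts (0.16, against -0.16 without the covariate, adjusted p 0.0291) and mast cells and basophils (0.71, adjusted p 0.0291). That fit used camera with the preset correlation of 0.01 alone. The correlation estimated in the main fit was 0.70 for neutrophils and 0.66 for T and NK cells. Relative to the mean of the 6 libraries, the neutrophil list lay at 0.11, 0.07 and -0.34 in wildtype replicates 1, 2 and 3. In Col6a1-/- replicates 1, 2 and 3 it lay at 0.35, -0.62 and 0.42. With the length and GC trend removed 12 lists passed, 4 higher and 8 lower, 10 of them shared with the 17. T and NK cells then lay lower (median -0.19, camera adjusted p 0.0127), opposite to the fit with the male share. Alveolar type 2 cells lay lower too (median -0.19, camera adjusted p 0.0026). In the main fit the median of the thymus list was -0.04 although camera gave the direction as higher.

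Within 5 Mb of Col6a1, 1 of 175 other tested genes was called, which was Col6a2, against 9 of 16703 elsewhere (Fisher's exact test, two-sided, p = 0.099). In a window of 2 Mb it was 1 of 60 genes against 9 of 16818 (Fisher's exact test, p = 0.035), in one of 10 Mb 1 of 234 against 9 of 16644 (Fisher's exact test, p = 0.13) and in one of 20 Mb 1 of 352 against 9 of 16526 (Fisher's exact test, p = 0.19). Counting genes at an unadjusted p under 0.01 instead, 8 of 175 lay within 5 Mb and 1204 of 16703 elsewhere (Fisher's exact test, p = 0.237), an odds ratio of 0.653 against 15.1 for the genes past the threshold. Without wildtype replicate 3, 6 of 175 genes within 5 Mb were called against 1376 of 16568 elsewhere, an odds ratio of 0.423 (Fisher's exact test, p = 0.0178), and without Col6a1-/- replicate 2 it was 1 of 174 against 45 of 16557, an odds ratio of 3.14 (Fisher's exact test, p = 0.382). In the fit without wildtype replicate 3, sex and genotype cannot be told apart. With the length and GC trend removed, 2 of 175 genes within 5 Mb were called against 64 of 16703 elsewhere, an odds ratio of 3.72 (Fisher's exact test, p = 0.15). These 2 were Col6a2 and Cirbp. Col6a2 itself was not called by limma without wildtype replicate 1 or 2 or Col6a1-/- replicate 1 or 3 (adjusted p of 0.181, 0.0934, 0.0531 and 0.302), nor was any other gene within 5 Mb, so these fits do not bear on the comparison.

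The sex-linked genes differed between pools, and sex was not given in the labels. Xist, which is transcribed from the inactive X chromosome of females, was at 16212, 16430.4 and 13592 normalized counts in wildtype replicates 1, 2 and 3 and at 12025, 28.4 and 10486 in Col6a1-/- replicates 1, 2 and 3. The mean of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, relative to Col6a1-/- replicate 2, was 0.347%, 3.35% and 51.5% in wildtype replicates 1, 2 and 3 and 72.5% and 51.1% in Col6a1-/- replicates 1 and 3. The Y-linked level was thus higher in the Col6a1-/- pools on average, with an exact permutation p of 0.2 for 3 against 3 libraries, where the smallest possible p is 0.1. With the male share as a covariate limma called no gene (1306 genes at an unadjusted p under 0.05). The log2 fold change of Col6a1 was then -1.24 with an SE of 0.15 and an adjusted p of 0.117.

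**Figure D4:**
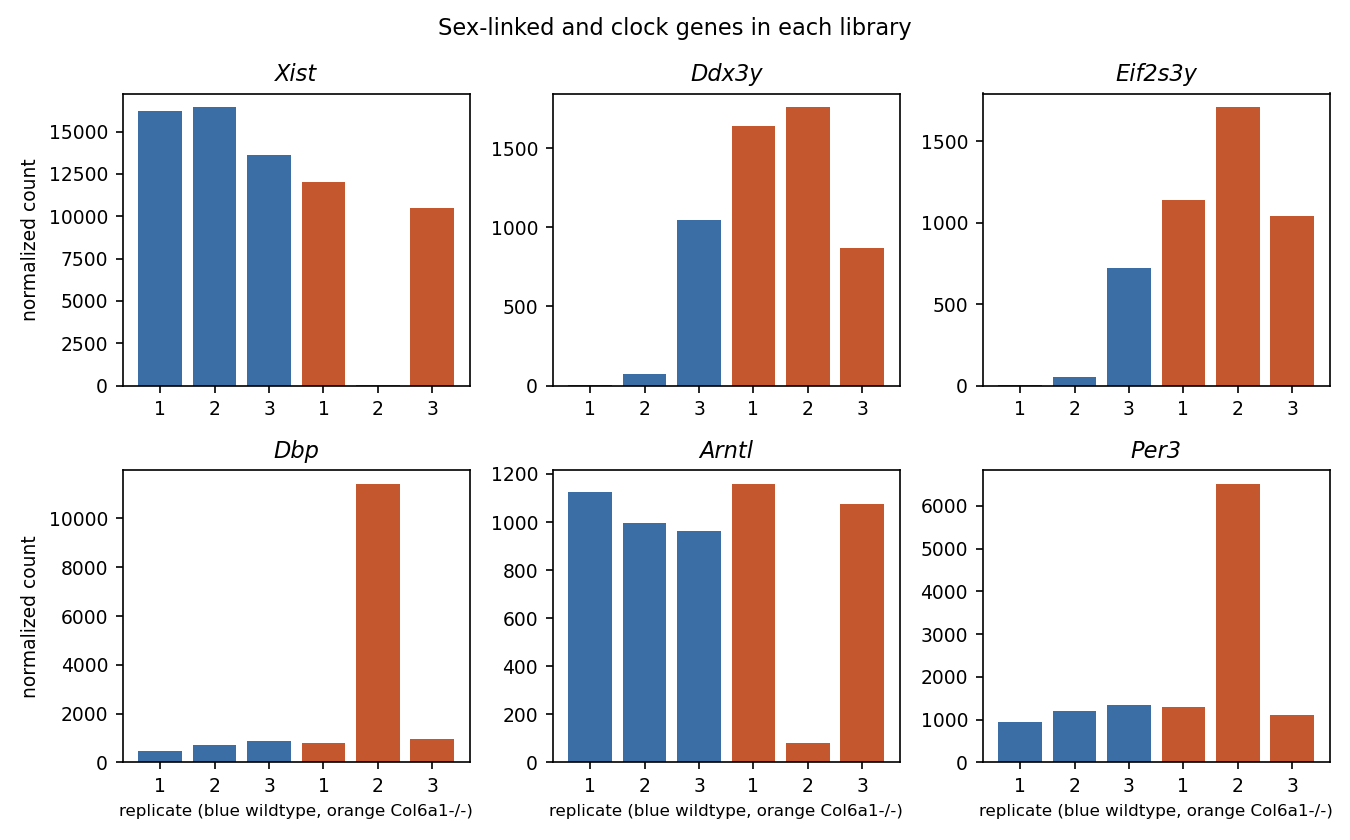
Normalized counts (vertical axes, linear and from 0) of Xist, the Y-linked genes Ddx3y and Eif2s3y, and the clock genes Dbp, Arntl and Per3 in each library, wildtype replicates 1 to 3 in blue and Col6a1-/- replicates 1 to 3 in orange. Col6a1-/- replicate 2 had 28.4 counts of Xist and 11404 of Dbp, where the other libraries had at most 957 of Dbp.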

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

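The fits with the male share, with the mixed-sex pools alone and with the length and GC trend removed and the DESeq2 fit on the genes of the main filter were chosen only after the data were examined. The count of 11 called genes became 93 without a filter on low values, 7 with a filter at 50, 26 with median centring, 30 with robust moderation, 3225 with library quality weights, 742 with DESeq2 on all 28476 genes above 0, 739 with DESeq2 on the genes of the main filter, 361 at an adjusted p under 0.1 and 5 at an absolute log2 fold change of at least 1. It lay between 0 and 1383 when single libraries were left out (0 without wildtype replicate 1 and without Col6a1-/- replicate 3, 2 without wildtype replicate 2, 13 and 47 without Col6a1-/- replicates 1 and 2, 1383 without wildtype replicate 3, where sex and genotype cannot be told apart). It was 0 with the male share, 67 with the trend removed (9 of the 11 shared), and 343 in the 3 mixed-sex pools, where 1 wildtype library is assumed to vary like the others and limma took the spread of each gene from the trend on mean level alone. The share of higher genes among those called, 27.3%, was 64.1% without wildtype replicate 3, 48.9% without Col6a1-/- replicate 2, 51.8% with quality weights, 51.0% in the mixed-sex pools and 42.9% with a filter at 50, and it lay between 11.5% and 38.8% in the other fits that called more than 2 genes. The cause of these changes was not tested. The stricter filter tested 14203 genes and the missing filter 28476. Pseudocounts of 0.5 and 5, quantile normalization and edgeR kept the count within 1.5 times (11, 12, 14 and 13).

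With the replicate number as a block, 7 genes were called, 6 of them shared with the 11. The labels do not say whether same-numbered pools belong together. The deviations of same-numbered libraries from their group means correlated at -0.136, 0.106 and -0.0059, and 2 of 6 libraries correlated best with their own number. These values gave no sign of a pairing but cannot exclude one. With the block 18 lists passed, the 17 among them.

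The log2 fold change of Col6a1 stayed between -1.08 and -0.94 with single libraries left out and was -1.24 with the male share. No list passed with an estimated correlation or in fry's directional test (0 of 40 in both), and 19 passed fry's mixed test. The dendritic cell and MHC class II list had a median of 0.026 with the male share. For called genes near Col6a1 the odds ratio within 5 Mb, 15.1, was 44.6 at 2 Mb, 11.2 at 10 Mb, 7.42 at 20 Mb, 3.72 with the length and GC trend removed, 0.653 for genes at an unadjusted p under 0.01, and between 0.423 and 31.6 with single libraries left out (0.423 without wildtype replicate 3). The 31.6, without wildtype replicate 2, comes from the continuity correction alone, since no gene near Col6a1 was called there (nor without Col6a1-/- replicate 1 or with the block), and where no gene at all was called there was no value. The authors' deposited table held 1277 genes at an adjusted p under 0.1.

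Named genes that turned sign had not passed the main test: Col6a4 (-0.39 to 0.17 with single libraries left out, positive without wildtype replicate 2 or Col6a1-/- replicate 3, and 0.15 with the trend removed), Col6a5 (-0.21 to 0.16 with single libraries left out, positive without wildtype replicate 3 or Col6a1-/- replicate 3, and 0.16 with the trend removed), Col6a6 (0.11) and Ndufa4 (-0.0086), the last 2 with the trend removed. Ndufa4 had an adjusted p of 0.108 in the main comparison and 0.0289 with DESeq2. At these depths and 3 libraries per genotype, 28% of simulated log2 changes of 0.5 and 96% of those of 1 were called. That simulation had 200 changed genes that varied independently and gave 178 calls, which makes the adjusted threshold looser than with the 11 real calls. In the real data Lama1 at -1.22 and Fgfbp3 at 1.03 did not pass (limma adjusted p 0.0815 and 0.0681). Changes of 1 and above could therefore be missed as well as smaller ones.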

Other observations

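The tests of the matrix and oxidative phosphorylation lists and those of the heat shock genes were chosen only after the results were seen; those of the 11 called genes were written before. Several chaperone genes lay lower in Col6a1-/- lungs together with Hsph1. A list of 18 targets of heat shock factor, chosen after seeing the data, had 14 members with lower estimates and a median log2 fold change of -0.21, with 4 members lower and 0 higher adjusted over the list alone. Stip1 stood at 70.5%, Hspa8 at 70.7% and Hsp90ab1 at 75.7% of wildtype, with limma adjusted p of 0.0693, 0.0942 and 0.0942 over all genes, and all 3 had no overlap between the genotypes. The cold-inducible genes Cirbp and Rbm3 were 1.5-fold and 1.28-fold the wildtype level in the same libraries (adjusted p 0.0681 and 0.14). Cirbp lies within 5 Mb of Col6a1 on chromosome 10 (start 80165985), so an effect of its position cannot be told apart here. The camera p of the heat shock list was 6.1e-05, and 0.0428 with an estimated correlation, on the data in which it was found, and 5 of the 18 genes are also in the immediate early and heat shock list, which did not pass.

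Endothelial genes went in both directions although the blood endothelium list as a whole did not pass. Adjusted over the list alone, 5 of its 22 members were lower, among them Vwf, and 1 was higher; Gja5 and Plvap stood at 68.9% and 76.3% of wildtype, and Sox17, a transcription factor gene of arterial endothelium, at 1.36-fold (adjusted p over all genes 0.0939, 0.0942 and 0.0815). In the lymphatic endothelium list Lyve1 stood at 63.8% of wildtype and Gpm6a, also a member of the mesothelium list, at 1.38-fold (limma adjusted p 0.0786 and 0.109). Adjusted over the lymphatic endothelium list alone, 2 members were lower and 1 higher.

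With the length and GC trend removed the median of the 18 heat shock targets was 1.5 times its former value (bootstrap interval over genes 0.902 to 3.38). With the male share as a covariate that median was 1.156 times its former value (0.683 to 2.88). Neither adjustment thus made the median smaller in size. The ratio with the male share cannot decide on the sex of the pools. The choice of the targets on these same data limits both ratios. Of 8 clock genes of large amplitude, 0 separated the genotypes, which argues against a clock shift shared by all 3 Col6a1-/- pools but cannot see a shift of 1 pool. Col6a1-/- replicate 2 did stand apart in clock genes (Dbp at 11404 normalized counts against 478 to 957), and without it the median of the targets was 1.02 times its former value (0.683 to 1.53), which argues against that pool as the whole cause. A difference in body temperature or handling at collection and an effect of the genotype may both be considered and were not tested; the intervals cover the spread over genes, not over animals.

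The lower matrix lists and the higher oxidative phosphorylation list were set against the same trend. Over the 154 members of 7 lists (6 matrix lists without the collagen VI chains, and oxidative phosphorylation), the median log2 fold change in the direction of the list was 0.20 before and 0.078 after the trend was removed, a ratio of 0.391 (bootstrap interval over genes 0.196 to 0.571), so that part of this pattern may follow transcript length and GC. The lists differed: the median went from -0.16 to -0.18 in the matrix proteases and inhibitors (ratio 1.14, interval 0.458 to 2.05), from -0.24 to -0.15 in the integrins (0.618, 0.346 to 0.95) and from -0.17 to -0.10 in the elastic fibre list (0.578, 0.0479 to 1.05), and the first 2 still passed camera (adjusted p 0.00482 and 0.00338), so the trend is not shown to account for these 3 lists. The other medians shrank more: from -0.27 to -0.074 in the basement membrane list (0.276, -0.0333 to 0.459) and from -0.15 to -0.014 in the interstitial collagens (0.0887, -0.541 to 0.421). That of the collagen VI partners went from -0.16 to -0.061 (0.389, -0.472 to 0.745). That of oxidative phosphorylation went from 0.15 to 0.0095 (0.0621, -0.178 to 0.269). The shift of these other lists may largely follow transcript length and GC. With the male share as a covariate the ratio over the 154 members was 1.52 (1.38 to 1.93), so the covariate did not reduce the pattern. This does not decide on the sex of the pools. The male share was higher in the Col6a1-/- pools on average, and the interval covers the spread over genes, not over pools. Whether the trend comes from RNA quality, library preparation or the genotype could not be told from these tables, because it was not the same within a genotype: rho of each library's deviation with length was 0.111, 0.143 and 0.486 in wildtype and 0.216, -0.303 and -0.532 in Col6a1-/- replicates 1 to 3 (exact permutation p of the difference 0.3, smallest possible 0.1).

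For the 11 called genes, the median ratio of the log2 fold change with the male share to that without it was 1.08 (bootstrap interval over genes 0.93 to 1.23). None was then called: Col6a1 went from -1.01 with an SE of 0.10 to -1.24 with an SE of 0.15, and the covariate takes 1 of few residual degrees of freedom. This ratio cannot decide on the sex of the pools. Genes were called for little spread within genotypes, where the male share varied, so a ratio near 1 was favoured beforehand. The interval covers the spread over genes, not over pools. With the length and GC trend removed the ratio was 0.823 (0.647 to 0.995) and 9 of the 11 were still called. The same selection limits this ratio, since the trend also varied within genotypes. The trend may contribute to many of the 11, since 9 of them had a smaller fold change after its removal, from 1.02 to 0.20 for Sult1d1 and from -1.01 to -0.90 for Col6a1. The genotypes gave 11 genes and the highest of the other 9 splits of the 6 libraries gave 1; 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

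Col6a1-/- replicate 2 stood apart in clock genes. Its normalized counts were 11404 for Dbp, 6507 for Per3, 80.9 for Arntl and 35.0 for Npas2, where the other 5 libraries had 478 to 957 for Dbp, 939.9 to 1347 for Per3, 962 to 1157 for Arntl and 438 to 652 for Npas2. The same library had the highest Y-linked and the lowest Xist level. In wildtype replicate 2 the Y-linked genes stood at 2.89% to 4.18% of their level in Col6a1-/- replicate 2, and in wildtype replicate 1 at 0.122% to 0.56%.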
